A study of Homo sapiens with 12 samples.

How the data were processed

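The authors sequenced RNA from human umbilical vein endothelial cells (HUVECs), primary cells from the lining of the umbilical vein. Cells were transfected with a control siRNA (siCtrl) or an siRNA against FOXO1 (siFOXO1) for 3 days. They were then kept static or exposed to low shear stress (LSS) of 3 dynes/cm2 for 24 h. Each of the 4 groups held 3 libraries, numbered 1 to 3, which gives 12 in all. The labels do not say whether replicates are separate cultures, so p-values measure only the spread between these samples.

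Per the submitters' processing notes, bcl2fastq, HISAT2 2.1.0, HTSeq 0.11.1 and DESeq2 1.24 were used, with the genome builds hg19 and GRCh38. The notes state neither the role of each nor their order. The deposited table is named for raw counts but holds counts per 1e6 reads (CPM) with 0.0001 added to every value. After that offset was removed, the values of each library were whole multiples of 1 step, which stands for 1 read. Among values under 2000 reads, 100% lay within 0.1 of a whole number of reads in every library. The step gives 11.91 to 16.87 M reads per library, and 1 read corresponds to 0.05929 to 0.08398 CPM. A count of 0 reads allows a level of up to 0.178 to 0.252 CPM (3 reads), a limit that covers counting error only.

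The table lists 24976 genes, of which 19804 carry a symbol in the file, 5132 were named from a reference table and 40 stayed unnamed. Coordinates are from the GRCh38 annotation. Genes with at least 0.5 CPM in at least 3 libraries were tested, 14762 in all. CPM values were divided by a factor per library from unweighted trimmed means of M-values (TMM; trims of 30% and 5%), written from its published definition, and are given as scaled CPM, mean ± SD, n = 3. The linear model of limma 3.58.1 in R 4.3.3 was fitted to log2(scaled CPM + 0.5) over all 12 libraries with 1 coefficient per group, and moderated with a mean-variance trend (eBayes; 8 residual and 5.53 prior degrees of freedom). P-values were adjusted over all genes tested (Benjamini-Hochberg), and a gene was called at an adjusted p under 0.05. Every fold change is the antilog of the fitted log2 difference, which averages log values and includes the 0.5 CPM. The 0.5 CPM makes folds smaller at low levels, but a fold can lie above or below the ratio of the printed means. Errors of log2 fold changes are standard errors (SE) of that model. Python 3.11.15 read the table and matplotlib 3.10.9 drew the figures.

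The comparisons were LSS against static in each siRNA arm, siFOXO1 against siCtrl in each condition, and the difference between both LSS responses (the interaction). The mean of both siFOXO1 effects was added after seeing the data. The comparisons, the lists and the rule for naming genes were chosen before the data were examined. The rule took FOXO1, then the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 CPM and group ranges that do not overlap (5 and 5 for LSS in siFOXO1 cells and the interaction). It also took up to 4 members with the smallest p-values from each of 21 gene lists. Some genes that the rule names are not reported here. These lists cover flow-induced KLF2 and KLF4 genes, adhesion and NF-κB inflammation, interferon response, FOXO targets, glycolysis, oxidative phosphorylation, fatty acid oxidation, cholesterol synthesis and uptake, MYC and ribosome biogenesis, cell cycle, endothelial identity, Notch and arterial genes, angiogenic tip cells, mesenchymal transition and TGF-β, YAP and TAZ targets, coagulation and fibrinolysis, ER and amino acid stress, autophagy and lysosome, hypoxia, NRF2 and oxidative stress, and the FOXO family. Another 6 lists hold markers of smooth muscle, fibroblasts, leukocytes, erythroid cells, epithelium and mesothelium, and lymphatic endothelium.

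Lists were tested with camera at a preset correlation of 0.01, two-sided, adjusted over the 24 lists with at least 3 tested genes. Camera with a correlation estimated from each list and fry, a rotation test that does not compare a list with other genes, were run beside it. The smooth muscle, leukocyte and erythroid lists had fewer than 3 tested genes and got no test. Counts of members are over all genes, with those adjusted over the list alone beside them for called lists and for LSS in siCtrl cells. Overlaps of calls are given beside the number expected by chance (the product of both counts over the genes tested). Where both comparisons share the siCtrl LSS libraries, they are also given beside 100 simulations in which siFOXO1 LSS did not differ from siCtrl LSS. Libraries of the same number under LSS varied together: deviations from the group means correlated across genes at 0.363, 0.479 and 0.69 for replicates 1, 2 and 3 of siCtrl and siFOXO1 LSS. For siCtrl and siFOXO1 static these correlations were 0.322, 0.124 and 0.0617. Between static and LSS they were 0.286, 0.181 and 0.0539 in siCtrl cells and 0.0966, 0.0957 and 0.0723 in siFOXO1 cells. This pairing comes from the values and not from the labels, and blocked counts are given beside a result where they move it by over 1.5 times. The mitochondrial share was compared with an exact permutation test, for which the smallest two-sided p in a comparison of 3 with 3 libraries is 0.1.

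The planned count tests of edgeR, DESeq2 and voom were not run, because whole reads recovered from the CPM values were not accepted by a check of the units, although the values allow them to be recovered. Alternatives were other scalings (median of ratios, upper quartile, none, quantile normalization), no filter, a filter of at least 1 CPM in 6 libraries, pseudocounts of 0.1 and 2 CPM, vooma precision weights, only the libraries of a comparison, a replicate block over all libraries or within each condition, and each library left out in turn. A further one left out both LSS replicate 3 libraries, which stood apart from the other LSS libraries. No scaling, quantile normalization, both pseudocounts, vooma, the block within condition and the removal of both libraries were chosen after seeing the data. The fit was tested on simulated data with the read depths of these libraries and known changes in 200 genes. It recovered between 14.1% and 23.1% of genes changed 1.5-fold, 50.0% to 63.6% of those changed 2-fold and 87.5% to 89.2% of those changed 4-fold in the 4 comparisons of 2 groups. For the interaction these shares were 1.52%, 34.3% and 83.1%. Between 3 and 9 unchanged genes were called per comparison. With so few changed genes the adjusted threshold is stricter than in the LSS comparisons of the real data. These shares therefore do not measure recovery for LSS.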

Results

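RNA was measured in 12 HUVEC libraries, 3 each from siCtrl static, siCtrl LSS, siFOXO1 static and siFOXO1 LSS cells. The series asks how FOXO1, a forkhead transcription factor, bears on flow, inflammatory and metabolic genes of endothelial cells under LSS. Reads per library ranged from 11.91 M (siCtrl static replicate 3) to 16.87 M (siFOXO1 static replicate 1). Static libraries lay between -54.41 and -46.63 on the first principal component, which held 68.7% of the variance, and LSS libraries between 45.27 and 56.57. The second component held 9.45%, and on it siCtrl LSS replicate 3 (-29.25) and siFOXO1 LSS replicate 3 (-44.69) stood apart from the other LSS libraries, which lay between 2.51 and 29.62. Mitochondrial transcripts took 5.03% ± 1.39 (SD, n = 3) of reads in siCtrl static cells and 2.23% ± 0.135 in siCtrl LSS cells. With siFOXO1 the shares were 5.39% ± 0.382 and 2.13% ± 0.235. In each arm the exact two-sided permutation test gave p = 0.1, the smallest it can give.

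FOXO1 itself (ENSG00000150907; chromosome 13, 40469953 to 40666597, minus strand) was lower in every siFOXO1 library than in every siCtrl library. In siCtrl static replicates 1, 2 and 3 it stood at 197.6, 214.3 and 209.6 scaled CPM, and in siCtrl LSS replicates at 171.9, 201 and 164.6. The siFOXO1 static replicates held 108, 72.66 and 94.94, and the siFOXO1 LSS replicates 47.94, 23.91 and 46.86. The siRNA lowered FOXO1 2.28-fold in static cells (log2 fold change -1.19, SE 0.22, adjusted p = 0.0475) and 4.68-fold under LSS (-2.23, SE 0.22, adjusted p = 0.000898). The static call was close to the threshold, and the adjusted p rose to between 0.05 and 0.248 when any of 9 libraries was left out: the 6 static ones (0.173, 0.228 and 0.181 without siCtrl replicates 1, 2 and 3, and 0.124, 0.248 and 0.134 without siFOXO1 replicates 1, 2 and 3), siCtrl LSS replicates 1 (0.0625) and 2 (0.05) and siFOXO1 LSS replicate 1 (0.0529). LSS changed FOXO1 by -0.21 in siCtrl cells (adjusted p = 0.456) and lowered it 2.38-fold in siFOXO1 cells (adjusted p = 0.000421). The other tested members of the FOXO family, FOXO3 and FOXO4, were called in none of the 4 comparisons of groups.

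**Figure D1:**
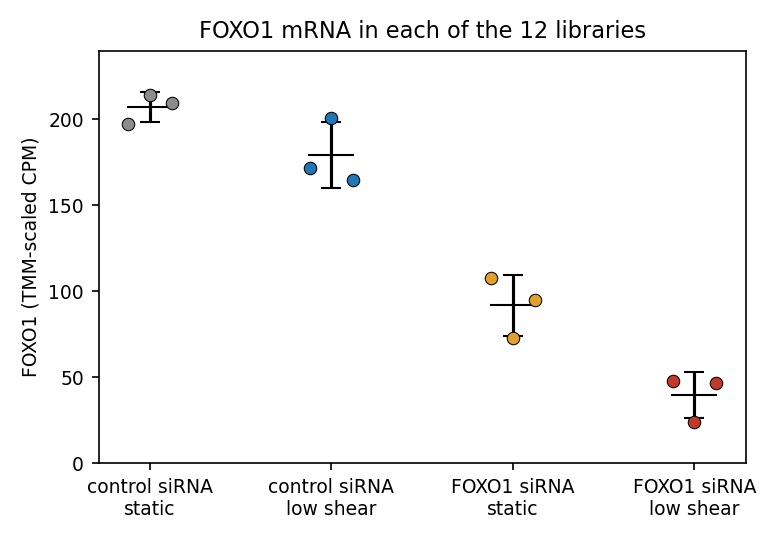
FOXO1 mRNA on the y axis (TMM-scaled CPM) in each library of the 4 groups on the x axis; points are libraries, the horizontal bar is the mean and the whiskers are 1 SD (n = 3). The siFOXO1 LSS libraries lie between 23.91 and 47.94, below all other libraries.

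LSS in siCtrl cells changed 45.7% of the tested genes, with HMOX1 and PTGS2 the largest rises and IL33 the largest fall among named genes. HMOX1, the heme-degrading oxygenase (chromosome 22, 35380361 to 35394214), rose 67.7-fold, from 61.8 ± 37.4 to 3986 ± 1609 scaled CPM (n = 3). PTGS2, the inducible cyclooxygenase (chromosome 1, 186671791 to 186680427), rose 65.6-fold, from 43.1 ± 8.08 to 2869 ± 631. IL33, a nuclear alarmin cytokine (chromosome 9, 6215786 to 6257983), fell 84.8-fold, from 269 ± 36.3 to 3.35 ± 3.10. In all, 6749 of 14762 genes changed, 3357 up and 3392 down, and 2697 of them by at least 2-fold (1244 up, 1453 down). Without scaling the median gene shifted by -0.18 and the split became 2416 up and 4551 down; 0 calls turned to the opposite direction.

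Among 23 tested members of the ER and amino acid stress list, 22 rose and 0 fell, with a median log2 fold change of 2.20 (camera adjusted p = 8.27e-12). The call was lost with an estimated correlation (adjusted p = 0.276 with an estimated correlation). DDIT3, the stress-induced factor CHOP, rose 36.6-fold to 98.4 ± 27.6 scaled CPM, PPP1R15A, which directs dephosphorylation of eIF2α, 15.2-fold, and the chaperone DNAJB9 11.6-fold. Of 19 NRF2 and oxidative stress genes 16 rose and 1 fell (median 1.55, adjusted p = 1.01e-06, and adjusted p = 0.276 with an estimated correlation). TXNRD1, thioredoxin reductase, rose 10.4-fold to 4364 ± 422, GCLM, of glutathione synthesis, 7.72-fold, and OSGIN1 19.9-fold. In the autophagy and lysosome list 16 of 26 rose and 1 fell (median 0.61, adjusted p = 7.09e-06, and adjusted p = 0.276 with an estimated correlation), among them GABARAPL1 (7.22-fold), the autophagy receptor SQSTM1 (5.03-fold) and MAP1LC3B (3.62-fold). Cholesterol synthesis and uptake genes rose in 13 of 24 cases and fell in 3 (median 0.79, adjusted p = 0.000365, and adjusted p = 0.324 with an estimated correlation). INSIG1, which holds back sterol synthesis, rose 6.29-fold, HMGCS1 4.46-fold and SC5D 2.3-fold. For hypoxia genes 8 of 17 rose and 1 fell (median 0.51, adjusted p = 0.0149, and adjusted p = 0.276 with an estimated correlation), with PDK1 up 4.72-fold and VEGFA 2.63-fold. The counts adjusted over the list alone were the same for ER stress, NRF2 and hypoxia, with 18 up and 1 down for autophagy and 15 up and 3 down for cholesterol.

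Mesenchymal transition and TGF-β genes rose in 11 of 25 cases and fell in 1, also when adjusted over the list alone (median 0.53, adjusted p = 0.00814, and adjusted p = 0.314 with an estimated correlation). SMAD6, an inhibitor of BMP signals, rose 6.49-fold, SNAI1, a repressor of epithelial genes, 4.95-fold and SKIL 2.64-fold. In the endothelial identity list 12 of 26 fell and 3 rose (13 and 3 adjusted over the list alone), with a median of -0.38 (adjusted p = 0.00375, and adjusted p = 0.314 with an estimated correlation). The tight junction gene CLDN5 fell 21.8-fold, the transcription factor gene SOX7 5.46-fold and CLEC14A 4.44-fold. The 3 that rose, named here after their values were seen, were FLT1 and ENG, receptors for VEGF and TGF-β ligands, and PLVAP, of endothelial fenestrae. Of 20 Notch and arterial genes 10 fell and 4 rose, also when adjusted over the list alone (median -0.79, adjusted p = 0.0341, and adjusted p = 0.465 with an estimated correlation). The arterial connexins GJA4 and GJA5 fell 32-fold and 27.8-fold, and the Notch ligand DLL4 6.64-fold. This call was lost without scaling (adjusted p = 0.122), without siCtrl LSS replicate 3 (0.057) and without both LSS replicate 3 libraries (0.073).

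Cell cycle genes fell in 23 of 38 cases and rose in 0, also when adjusted over the list alone (median -0.71, adjusted p = 7.09e-06, and adjusted p = 0.541 with an estimated correlation). PCNA, the replication clamp, fell 2.84-fold, RRM2 3.38-fold and UHRF1 6.84-fold. MYC and ribosome biogenesis genes fell in 15 of 29 cases and rose in 2 (17 and 2 adjusted over the list alone; median -0.42, adjusted p = 0.00142, and adjusted p = 0.395 with an estimated correlation), with PUS7 down 3.82-fold. Interferon response genes fell in 18 of 29 cases and rose in 3 (19 and 4 adjusted over the list alone; median -0.87, adjusted p = 0.000222, and adjusted p = 0.395 with an estimated correlation). OAS2, a sensor of double-stranded RNA, fell 7.78-fold, IFIH1 6.16-fold and GBP1 5.82-fold.

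Other lists held large changes in both directions and were not called under LSS in siCtrl cells. Among flow-induced genes 9 of 19 rose and 5 fell (adjusted p = 0.272). KLF4 rose 21-fold and CYP1B1 25.1-fold, while GJA4 fell. KLF2 and NOS3, picked after their values were seen, stood at 21.4 ± 4.77 and 64.0 ± 7.76 scaled CPM in static cells; KLF2 rose by 1.67 (SE 0.23) and NOS3, the endothelial nitric oxide synthase, fell by 2.34 (SE 0.24) on the log2 scale. In the adhesion and NF-κB list 6 of 23 rose and 6 fell (6 and 7 adjusted over the list alone; adjusted p = 0.673). PTGS2 and the neutrophil chemokine CXCL8 (39.5-fold) rose, and the monocyte chemokine CCL2 fell 7.07-fold. Of 30 FOXO targets 11 rose and 9 fell (adjusted p = 0.77). SESN3 fell 17.2-fold and TXNIP 9.53-fold, whereas SPRY2 rose 6.91-fold and KLF6 3.34-fold. The median of that list was 0.08, its mean -0.12. Glycolysis (8 of 24 up, 7 down, adjusted p = 0.891), oxidative phosphorylation (5 of 53 up, 7 down, 5 and 3 adjusted over the list alone, adjusted p = 0.945) and fatty acid oxidation (6 of 26 up, 7 down, adjusted p = 0.945) were split too. SLC2A3, a glucose transporter, rose 3.31-fold and SLC16A1, a lactate transporter, fell 2.59-fold. Of the 13 mitochondrial mRNAs, a group added after seeing the data, 12 fell (median -1.41). Their reads are part of the lower mitochondrial share, so this is not a separate observation. The tip cell list (12 of 25 up, 5 down, adjusted p = 0.296) held APLN, down 27.4-fold. YAP and TAZ targets (8 of 22 up, 7 down, adjusted p = 0.891; median -0.28, mean 0.04) and coagulation genes (6 of 22 up, 6 down, 6 and 7 adjusted over the list alone, adjusted p = 0.9; median -0.18, mean 0.32) both held F3, tissue factor, up 35.2-fold from 0.842 ± 0.366 scaled CPM. For the uncalled lists with no second count, the count adjusted over the list alone was the same. The FOXO family, with 3 tested members, had 0 calls by limma (adjusted p = 0.77).

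Markers of other cell types did not rise: of 16 tested outside the lymphatic list 0 rose and 5 fell (SMTN, PDGFRB, THY1, KRT18 and KRT19, named after their values were seen). The most abundant were SMTN (59.4 ± 5.04 in static and 31.3 ± 6.76 scaled CPM in LSS siCtrl cells) for smooth muscle, COL3A1 (39.3 ± 10.8 and 27.4 ± 5.40) for fibroblasts and KRT18 (53.9 ± 0.607 and 19.5 ± 3.13) for epithelium. CD14, of leukocytes, stood at 0.113 ± 0.111 and 0.0524 ± 0.0908, under the limit that 0 reads allows, and 0 erythroid markers passed the filter. Fibroblast (0 of 9 up, 2 down, 0 and 0 adjusted over the list alone, adjusted p = 0.328), epithelial and mesothelial (0 of 5 up, 2 down, adjusted p = 0.201) and lymphatic lists (1 of 4 up, 2 down, 2 and 2 adjusted over the list alone, adjusted p = 0.891) were not called. LYVE1, the top lymphatic marker, stood at 179 ± 75.5 and 54.2 ± 43.0. With camera 11 of 24 lists were called, with an estimated correlation 0, and with fry 16. NGFR also stood among the largest rises; it had 0 reads in all siCtrl static libraries and 29.79 ± 21.25 scaled CPM under LSS, so no fold is given.

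**Figure D2:**
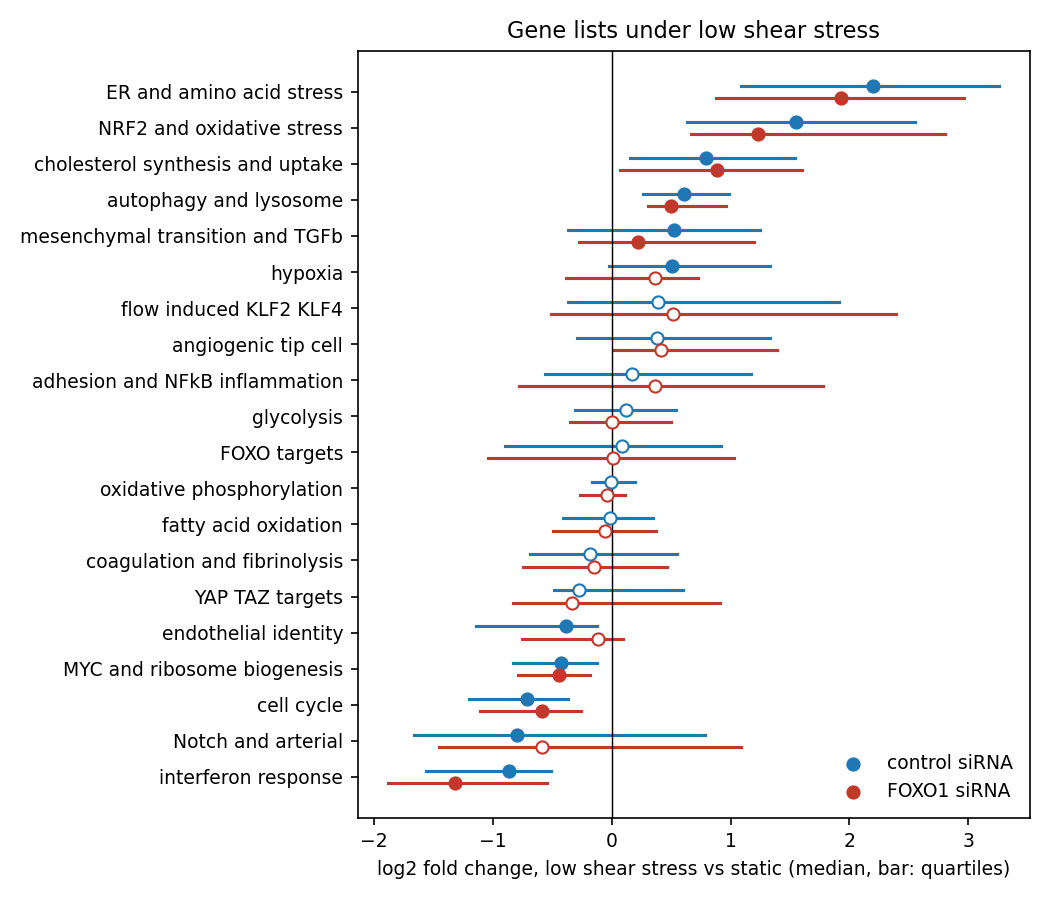
Median log2 fold change of LSS against static (x axis) for the members of each gene list (y axis) in siCtrl (blue) and siFOXO1 cells (red); bars span the quartiles over the genes of a list, and filled points passed camera with the preset correlation. ER and amino acid stress lies at 2.20 and 1.93 and interferon response at -0.87 and -1.32.

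In siFOXO1 cells LSS moved largely the genes that it moved in siCtrl cells. PTGS2 rose 70.9-fold, from 51.4 ± 12.02 to 3645 ± 603 scaled CPM (n = 3), HMOX1 57.1-fold to 5210 ± 1897 and KLF4 30.6-fold to 189 ± 54.8. IL33 fell 78.8-fold, GJA5 52-fold and DEPP1, a FOXO-regulated autophagy gene, 50.5-fold, from 83.4 ± 21.5 to 1.37 ± 1.239. In all 6983 genes changed (3466 up, 3517 down), 2872 by at least 2-fold (1285 up, 1587 down); without scaling the median shifted by -0.23 and the split was 2306 up and 5044 down. Both arms shared 5716 calls in the same direction, against 1600 expected by chance, and 0 in opposite directions. Log2 fold changes correlated across genes, which are not independent replicates, with Pearson r = 0.941 and Spearman rho = 0.92. The median ratio of the siFOXO1 to the siCtrl change was 0.981 over genes called in siCtrl cells, and the median inverse ratio 0.92 over genes called in siFOXO1 cells.

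Camera called 8 lists for LSS in siFOXO1 cells. Up were ER stress (21 of 23 rose, 0 fell, median 1.93, adjusted p = 4.78e-10), NRF2 (15 of 19 rose, 1 fell, median 1.23, adjusted p = 1.62e-06), autophagy (18 of 26 rose, 1 fell, median 0.50, adjusted p = 2.53e-05), cholesterol (14 of 24 rose, 3 fell, median 0.88, adjusted p = 0.000281) and mesenchymal transition (11 of 25 rose, 1 fell, median 0.22, adjusted p = 0.00713). Without scaling the median of the mesenchymal list was -0.01. Down were interferon response (20 of 29 fell, 3 rose, median -1.32, adjusted p = 3e-05), cell cycle (18 of 38 fell, 0 rose, median -0.59, adjusted p = 8.51e-05) and MYC and ribosome biogenesis (14 of 29 fell, 2 rose, median -0.44, adjusted p = 0.00362). All 8 calls were lost with an estimated correlation (adjusted p = 0.379 for ER stress, NRF2, autophagy and mesenchymal genes, 0.433 for cholesterol, 0.442 for interferon, 0.56 for cell cycle and 0.453 for MYC and ribosome biogenesis). Among stress genes PPP1R15A rose 19.6-fold, the cystine transporter gene SLC7A11 20.1-fold, OSGIN1 23.1-fold and TXNRD1 12.2-fold, and HMGCS1 rose 4.88-fold; OAS2 fell 6.02-fold, UHRF1 8.51-fold and PUS7 2.88-fold. Adjusted over the list alone, the counts were the same for ER stress, autophagy and cholesterol, with 16 up and 1 down for NRF2, 12 up and 3 down for mesenchymal transition, 3 up and 21 down for interferon, 0 up and 20 down for cell cycle and 2 up and 15 down for MYC and ribosome biogenesis. Endothelial identity (7 of 26 fell, 3 rose, adjusted p = 0.139), Notch and arterial (10 of 20 fell, 6 rose, adjusted p = 0.111) and hypoxia (6 of 17 rose, 4 fell, adjusted p = 0.167) were not called by camera in this arm. Fry did call endothelial identity (adjusted p = 0.000669) and hypoxia (adjusted p = 0.000608) here. All 13 mitochondrial mRNAs fell (median -1.79).

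**Figure D3:**
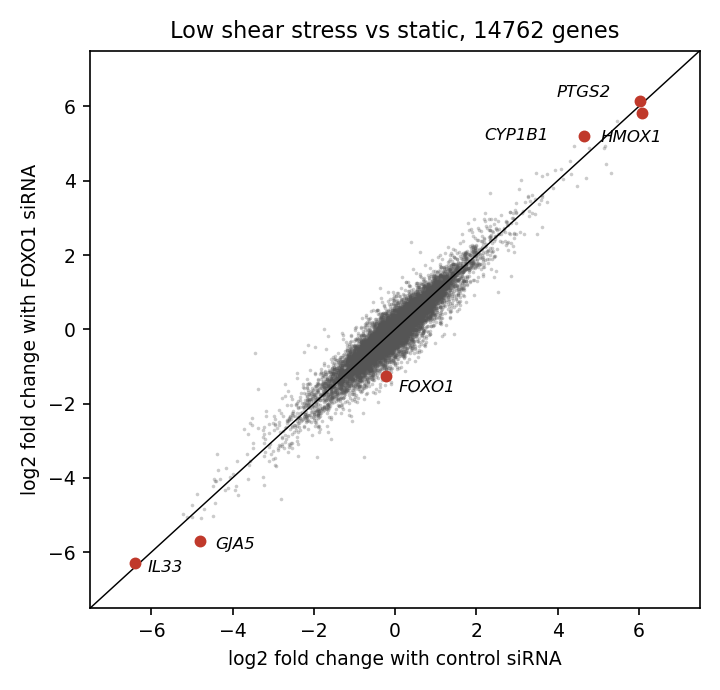
Log2 fold change of LSS against static in siCtrl cells (x axis) and in siFOXO1 cells (y axis) for 14762 genes (grey points), with named genes in red and the line of equal change. IL33 (-6.41 and -6.30) and PTGS2 (6.04 and 6.15) lie on the line; FOXO1 (-0.21 and -1.25) lies below it.

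FOXO1 siRNA in static cells changed 3 named genes that kept the call without any 1 library: ACSM3 and SEMA3G fell and IFI44L rose. ACSM3, an acyl-CoA synthetase (chromosome 16, 20610243 to 20797581), fell 5.31-fold, from 74.0 ± 15.6 to 13.7 ± 3.69 scaled CPM (n = 3, adjusted p = 0.00384). SEMA3G, a secreted semaphorin (chromosome 3, 52433053 to 52445085), fell 4.69-fold from 24.2 ± 5.69 to 4.67 ± 0.266. FABP4, a fatty acid carrier (chromosome 8, 81478419 to 81483263), fell 2.99-fold from 172 ± 21.6. IFI44L, an interferon-induced gene (chromosome 1, 78619922 to 78646145), rose 5.99-fold from 6.82 ± 2.03 to 42.6 ± 7.97 (adjusted p = 0.00384). Other rises were the matrix genes FBLN2 (5.09-fold) and ADAMTS5 (8.37-fold), the apelin receptor gene APLNR (4.24-fold) and the connexin gene GJA5 (3.14-fold). A2M, a protease inhibitor (3.5-fold), and PGF, placental growth factor (2.8-fold), fell as well. In all 47 genes changed, 24 up and 23 down, and 37 by at least 2-fold (20 up, 17 down); 948 had an unadjusted p under 0.05, against 738 expected by chance.

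Of 29 interferon response genes 3 rose in static cells (IFI44L, IFIT1 and IFITM1) and 0 fell; adjusted over the list alone, 11 rose. The median was 0.44 (camera adjusted p = 1.7e-12, and adjusted p = 0.255 with an estimated correlation). Flow-induced genes had a median of 0.33 (adjusted p = 0.000216, and adjusted p = 0.255 with an estimated correlation) with 0 of 19 called by limma, and 2 rose when adjusted over the list alone; PLPP3, a lipid phosphatase, stood at 87.6 ± 6.72 and 136 ± 14.9 (adjusted p = 0.0856). The 5 epithelial and mesothelial markers had a median of 0.71 (adjusted p = 0.00528, and adjusted p = 0.512 with an estimated correlation), with 0 called and 1 adjusted over the list alone; KRT18 stood at 53.9 ± 0.607 and 63.2 ± 7.71. The tip cell list was called down (1 of 25 rose, 1 fell, 2 and 4 adjusted over the list alone; median -0.10, adjusted p = 0.0428, and adjusted p = 0.546 with an estimated correlation), with PGF down and APLNR up. That call was lost without siCtrl static replicates 2 (adjusted p = 0.0978) and 3 (0.0707), siCtrl LSS replicate 1 (0.0552) and siFOXO1 static replicates 1 (0.149) and 3 (0.0936). Median-of-ratios scaling (0.0569), the stricter filter (0.0533) and a pseudocount of 2 (0.0571) ended it too, and the median was -0.03 without siFOXO1 static replicate 1. Among 30 FOXO targets TXNIP, a thioredoxin inhibitor, rose 1.88-fold from 116 ± 21.4 to 216 ± 7.67, and 0 fell (1 and 2 adjusted over the list alone; adjusted p = 0.733; median 0.03, mean -0.04). Glycolysis (adjusted p = 0.54), oxidative phosphorylation (0.54), fatty acid oxidation (0.414) and adhesion genes (0.959) were not called, with 0 of their members past limma's threshold. With fry 0 lists were called.

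The count in static cells moved in both directions with the settings. It was 351 genes with only the static libraries, whereas the spread in the main fit also comes from the LSS libraries. It was 110 with the replicate block, 494 with the block within each condition and 170 without both LSS replicate 3 libraries. The count was 25 with the stricter filter and 14 and 73 with pseudocounts of 0.1 and 2. It fell to 6, 4 and 8 without siCtrl static replicates 1, 2 and 3, to 7, 3 and 3 without siFOXO1 static replicates 1, 2 and 3 and to 26 without siFOXO1 LSS replicate 1, and it reached 89 without siCtrl LSS replicate 3 and 75 without siFOXO1 LSS replicate 3. Of 21 named genes called, IFI44L, ACSM3 and SEMA3G kept the call without any 1 library and 18 lost it without at least 1, which include FOXO1, ADAMTS5, FBLN2, APLNR, IFIT1, GJA5, IFITM1, A2M, FABP4, PGF and TXNIP.

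Under LSS, FOXO1 siRNA lowered FABP4 and FABP5 and raised ADAMTS18 and SLCO2A1. FABP4 fell 6.45-fold, from 56.9 ± 23.6 to 8.12 ± 2.50 scaled CPM (n = 3, adjusted p = 0.000898), and its relative FABP5 fell 2.97-fold, from 41.6 ± 9.94 to 13.7 ± 3.63. ADAMTS18, a secreted metalloprotease, rose 9.13-fold from 9.09 ± 6.73 to 80.0 ± 42.5 (adjusted p = 0.00417). SLCO2A1, which takes up prostaglandins, rose 7.97-fold from 7.67 ± 5.44 to 56.2 ± 17.7 (adjusted p = 0.014). DEPP1 fell 6.28-fold, ACSM3 5.16-fold, SEMA3G 4.54-fold, the immediate early gene EGR1 4.1-fold and A2M 3.6-fold; ADAMTS1 rose 4.49-fold, IFI44L 4.21-fold and MN1 3.48-fold. In all 97 genes changed, 46 up and 51 down, and 54 by at least 2-fold (26 up, 28 down). Without scaling the split was 40 up and 92 down.

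Flow-induced genes had a median of 0.43 under LSS (camera adjusted p = 1.91e-05, and adjusted p = 0.264 with an estimated correlation). TEK, the angiopoietin receptor, was the 1 of 19 that rose (1.64-fold, from 270 ± 52.7 to 441 ± 58.2); adjusted over the list alone 6 rose. Interferon response genes had a median of 0.47 (adjusted p = 3.25e-05, and adjusted p = 0.491 with an estimated correlation), with IFI44L and OAS2 (3.57-fold) the 2 of 29 that rose and 0 that fell (5 and 1 adjusted over the list alone). Mesenchymal transition genes had a median of 0.27 (adjusted p = 0.0158, and adjusted p = 0.462 with an estimated correlation), with 0 of 25 called by limma and 1 up adjusted over the list alone. Epithelial and mesothelial markers had a median of 0.62 (adjusted p = 0.00358, and adjusted p = 0.462 with an estimated correlation), with 0 of 5 called and 3 adjusted over the list alone; KRT18 stood at 19.5 ± 3.13 and 30.8 ± 8.61. ER and amino acid stress genes were called down (median -0.29, adjusted p = 0.00421, and adjusted p = 0.622 with an estimated correlation) with 0 of 23 called by limma; HERPUD1 stood at 319 ± 56.5 and 226 ± 43.25. The calls ended without siCtrl LSS replicate 1 (adjusted p = 0.0552 for ER stress and 0.064 for epithelial markers), siCtrl LSS replicate 2 (0.187 for ER stress and 0.105 for mesenchymal genes), siFOXO1 LSS replicate 1 (0.0588 for mesenchymal genes) and siFOXO1 LSS replicate 3 (0.744, 0.0552 and 0.0552 for ER stress, mesenchymal genes and epithelial markers). The ER stress median was then -0.15, -0.17 and -0.07 without siCtrl LSS replicates 1 and 2 and siFOXO1 LSS replicate 3. Quantile normalization also ended the mesenchymal call (adjusted p = 0.0514). Of glycolysis genes PGAM1 fell 2.4-fold from 112 ± 19.6 (1 of 24; list adjusted p = 0.191), and in the endothelial identity list EMCN (1.71-fold) and TEK rose (2 of 26; list adjusted p = 0.0559). In the coagulation list A2M fell and PTGS1, the constitutive cyclooxygenase, rose 2.27-fold (list adjusted p = 0.865), and in the lysosome list the protease gene CTSB fell 1.53-fold (list adjusted p = 0.271). FOXO targets had 0 of 30 called by limma and 2 up and 4 down adjusted over the list alone (adjusted p = 0.12); ANGPT2 stood at 55.1 ± 33.6 and 14.8 ± 7.62. With fry 0 lists were called.

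With only the siCtrl and siFOXO1 LSS libraries in the fit, limma called 0 genes under LSS, and FOXO1 lost its call (-2.23, adjusted p = 0.089). The main fit uses 1 spread for all 12 libraries, so its 97 calls under LSS rest in part on the spread of the static libraries. The count was 1228 with a replicate block within each condition and 221 without both LSS replicate 3 libraries. With the replicate number as a block over all libraries it was 314, beside 97 without, and 7 lists were called beside 5, with endothelial identity (adjusted p = 0.0291) and FOXO targets (adjusted p = 0.0444) added. Without the block these lists had adjusted p = 0.559 and 0.462 with an estimated correlation. Among all lists, members called with the block and not without it included ANGPT2, an antagonist of TEK (-1.73, adjusted p = 0.0331), of the FOXO target and tip cell lists. Others were the chemokine receptor gene CXCR4 (-2.83, adjusted p = 0.0183) of the Notch and tip cell lists and the leukocyte adhesion gene ICAM1 (0.95, adjusted p = 0.0224) of the adhesion list. PLPP3 (0.64, adjusted p = 0.0081), of the flow-induced list, was called too. The count was 52, 56 and 181 without siCtrl LSS replicates 1, 2 and 3, 33 without siFOXO1 LSS replicate 2, 59 without siCtrl static replicate 2 and 56 without siFOXO1 static replicate 3. Of 27 named genes called, 14 kept the call without any 1 library, among them ADAMTS18, SLCO2A1, IFI44L, FABP4, ACSM3, SEMA3G, A2M and PGAM1, and 13 lost it without at least 1, among them ADAMTS1, DEPP1, EGR1, TEK, OAS2, EMCN, PTGS1 and CTSB.

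**Figure D4:**
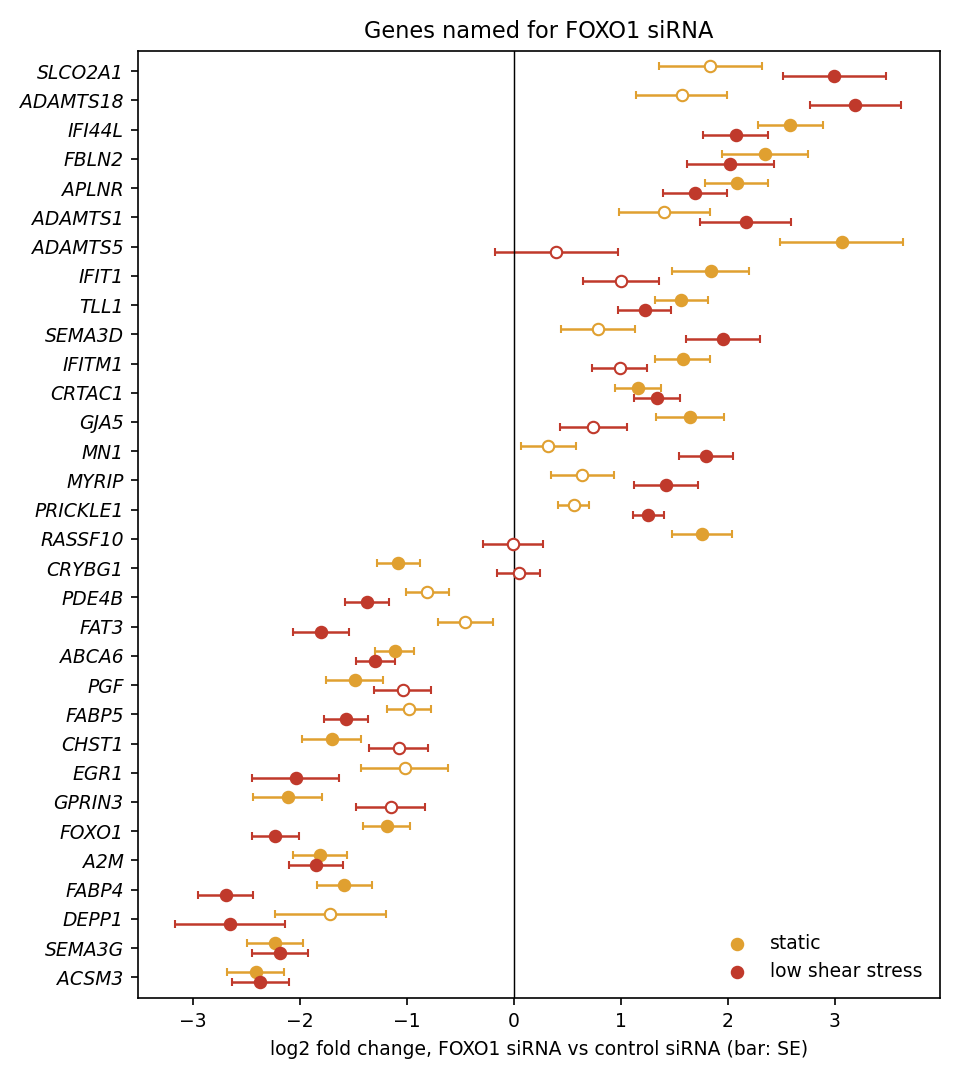
Log2 fold change of siFOXO1 against siCtrl (x axis) in static cells (orange) and under LSS (red) for genes among the largest called changes in either condition (y axis); bars are 1 SE and filled points passed an adjusted p under 0.05. ACSM3 lies at -2.41 and -2.37, and IFI44L at 2.58 and 2.07.

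Across both conditions FOXO1 siRNA changed 18 genes in the same direction, 8 up and 10 down, against 0.154 expected by chance, and 0 in opposite directions. Besides FOXO1 the shared falls included ACSM3, SEMA3G, FABP4, A2M and ABCA6, and the shared rises IFI44L, FBLN2, APLNR, TLL1 and CRTAC1. Log2 fold changes correlated across all genes with r = 0.489 and rho = 0.39. The overlap was 65 with the replicate block, 287 with the block within each condition, 0 with only the libraries of each comparison, 29 with quantile normalization, 10 with a pseudocount of 0.1 and 57 without both LSS replicate 3 libraries. It was 3, 4 and 5 without siCtrl static replicates 1, 2 and 3, 6, 3 and 3 without siFOXO1 static replicates 1, 2 and 3, 11 and 31 without siCtrl LSS replicates 1 and 3 and 8 without siFOXO1 LSS replicate 2.

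Of genes that LSS changed in siCtrl cells, FOXO1 siRNA under LSS changed 40 in the opposite direction (22.2 expected by chance) and 33 in the same direction (22.2 expected). SLCO2A1 (-1.69 with LSS and 2.99 with siRNA), ADAMTS18 (-2.24 and 3.19), OAS2 (-2.96 and 1.83) and KCTD12 (-2.40 and 1.22) were among 26 that LSS lowered and the siRNA raised. EGR1 (1.95 and -2.04) and NOX4 (1.70 and -0.98), an NADPH oxidase gene, were among 14 that went the other way. KCTD12 and NOX4 were picked after their values were seen. Both contrasts share the siCtrl LSS libraries, which alone gives opposite signs. The 100 simulations with no siRNA effect gave 0 opposite calls and on average 0.02 calls in the same direction (0 to 1). With so few calls they cannot judge how the real calls part between both directions. The covariance of the log2 fold changes was -0.0249, within the -0.0344 to -0.0209 of 100 simulations with no siRNA effect (mean -0.0271). Pearson r across genes was -0.0926, outside the simulated -0.162 to -0.102 and nearer to 0. The opposite sign was found in 53.3% of LSS-called genes, below the simulated 54.9% to 58.5% (mean 56.5%). The simulated libraries carried no deviations shared by same-numbered LSS libraries, so these ranges hold for unpaired libraries. The opposite count was 123 with the replicate block, 0 with only the libraries of each comparison and 98 without both LSS replicate 3 libraries. It was 20, 23 and 91 without siCtrl LSS replicates 1, 2 and 3, 25 without siCtrl static replicate 2 or 3, 14 without siFOXO1 LSS replicate 2 and 24 without siFOXO1 static replicate 3. The 3 control libraries were too few to be split between both contrasts.

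The interaction asks whether the LSS response differed with FOXO1 siRNA. Limma called 0 genes, also with a replicate block over all libraries, and 40 (21 up, 19 down) with a replicate block within each condition, a setting chosen after seeing the data. Without a block the limma count was 0, and the smallest adjusted p was 0.074. At an unadjusted p under 0.05 there were 444 genes, fewer than the 738 expected by chance. This fit leaves out the pairing of same-numbered LSS libraries, so its 0 calls do not show that the responses were alike. FOXO1, which the naming rule took in advance, had an interaction of -1.04 without a block (SE 0.31, limma unadjusted p = 0.00535, adjusted p = 1). Its change with the siRNA was -1.187 in static cells and -2.226 under LSS. Differences between the siRNA effects of both conditions therefore cannot be told apart from this unequal knockdown. Camera called 3 lists, each with adjusted p = 0.0467 and 0 called genes: endothelial identity (median 0.14, and adjusted p = 0.961 with an estimated correlation), ER and amino acid stress (median -0.26, and adjusted p = 0.961 with an estimated correlation) and hypoxia (median -0.15, and adjusted p = 0.771 with an estimated correlation). Adjusted over the list alone, 1 endothelial identity gene rose. Fry called 0 lists. Without siFOXO1 LSS replicate 3 the ER stress median was 0.05 and the hypoxia median -0.03. The number of lists was 0 without siCtrl LSS replicate 2, 1 without siFOXO1 static replicate 1 and 5 without siFOXO1 LSS replicate 1 or 3, and 2 genes were called without siFOXO1 LSS replicate 3.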

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

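Tests of RNA from other cell types, of scaling, of a shared run or culture and of the siRNA itself were chosen after the result was seen. A difference between the LSS responses of both siRNA arms singled out 4 results. FOXO1 had an interaction of -1.04 (SE 0.31, limma unadjusted p = 0.00535, adjusted p = 1). The list medians of the interaction were 0.138 for endothelial identity, -0.257 for ER and amino acid stress and -0.15 for hypoxia, each with a camera adjusted p = 0.0467 (adjusted p = 0.961, 0.961 and 0.771 with an estimated correlation). Without siFOXO1 LSS replicate 3 the ER stress median turned to 0.0479 and the hypoxia median shrank to -0.0287. These list calls were lost in 7, 7 and 10 of 24 other settings, with the highest adjusted p at 0.215 without siFOXO1 LSS replicate 2 for endothelial identity and at 0.945 and 0.272 without siFOXO1 LSS replicate 3 for ER stress and hypoxia. Chance was not excluded for the interaction in the fit without a block, over splits that ignore the pairs of LSS libraries: 59 of 100 splits gave at least its 444 genes at an unadjusted p under 0.05 (highest other 2857), and 81 of 100 gave at least 3 lists (highest other 10). Of the 39 splits that part all LSS pairs, 9 gave at least 444 genes (highest other 1076) and 29 at least 3 lists. A replicate block within each condition called 40 genes, and no splits were run with it.

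For comparisons of 3 with 3 libraries, 10 splits are too few for a share under 0.05. LSS in siCtrl cells gave 6749 genes against at most 0 in other splits (1 of 10 as large) and 11 lists against 10 (1 of 10). LSS in siFOXO1 cells gave 6983 genes against 0 (1 of 10) and 8 lists against 9 (4 of 10). FOXO1 siRNA in static cells gave 47 genes against 0 (1 of 10) and 4 lists against 8 (8 of 10). FOXO1 siRNA under LSS gave 97 genes against 768 (3 of 10) and 5 lists against 7 (7 of 10). The split with 768 genes set siCtrl LSS replicates 1 and 2 and siFOXO1 LSS replicate 2 against the rest, which points to a structure of the samples. Among the 4 splits that part all 3 same-numbered pairs, the real one gave 97 genes and the highest other 0, and with the replicate block the count was 314. The siRNA effect averaged over both conditions was a comparison added after seeing the data. For it only the real split, 1 of 100, gave as many as 332 genes (highest other 54), which argues against chance for the genes. Chance was not excluded for lists (5, highest other 9, 44 of 100).

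Under LSS in siCtrl cells the ER stress and NRF2 lists were called up and the endothelial identity list down with the preset correlation (adjusted p = 0.276, 0.276 and 0.314 with an estimated correlation). After a trend on transcript length and GC content was removed, the gap between the ER stress and endothelial identity medians was 2.55 (2.58 before). The endothelial median was then -0.259 (-0.384 before). The 95% interval of the gap, 1.6 to 3.36, came from 1000 resamples of the list genes and does not measure the spread between libraries. These values argue against such a bias as the whole cause. Of 16 markers of other cell types 0 rose by limma and 5 fell, which argues against RNA from other cells. Over the other scalings the endothelial median stayed at or below -0.326 and the ER stress median at or above 2.01. The median of all genes moved only between -0.182 without scaling and 0.0384 with upper-quartile scaling. These values argue only against the choice among these scalings as the cause. The comparison and the lists were chosen in advance. Fry, which does not compare a list with other genes, gave adjusted p = 4.28e-05 for ER stress and 6.81e-05 for endothelial identity. Both lists thus differed between the LSS and static libraries of siCtrl cells. The camera calls, which compare a list with other genes, were lost with an estimated correlation. A shift of the lists beyond other genes therefore remains a hypothesis, and the other causes were tested on the same data.

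Both LSS replicate 3 libraries stood apart from the other LSS libraries. Sequencing depth is argued against, since their deviations correlated at 0.662 after thinning to equal depth and at 0.69 before. A run or culture shared by libraries of the same number could be the source: the lowest correlation of same-numbered LSS libraries was 0.363 and the highest of differently numbered ones 0.112. The labels give no run or culture, so this stays open.

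The interferon response list had a positive median with FOXO1 siRNA in both conditions (0.438 averaged), with 3 of 29 genes called in static cells and 2 of 29 under LSS. The list calls were lost with an estimated correlation (adjusted p = 0.255, 0.491 and 0.314 in static cells, under LSS and averaged). A single library is argued against, since the median was at least 0.29, its value without siFOXO1 LSS replicate 3. Chance was not excluded over all splits, as 7 of 100 gave a median as far from 0 (highest other 0.516), but among the 39 of these that part all same-numbered LSS pairs, a subset chosen after the result was seen, the highest other was 0.385. A response to the siRNA itself and loss of FOXO1 cannot be told apart with 1 siRNA per arm; the list median was 1.05 times as large under LSS as in static cells, while the FOXO1 change was 1.88 times as large.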

How the results depend on the processing

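The alternatives chosen after seeing the data were no scaling, quantile normalization, pseudocounts of 0.1 and 2, vooma weights, the block within each condition and both LSS replicate 3 libraries left out. No count, FOXO1 value or named gene call turned to the opposite direction. Of the list medians behind a call, 2 changed sign: mesenchymal genes for LSS in siFOXO1 cells without scaling (-0.00958) and ER stress for the interaction without siFOXO1 LSS replicate 3 (0.0479). Of 210 named gene results called, 4826 of 5085 alternative values kept the call and 259 lost it. Whichever 1 library was left out, all 85 named calls for LSS in siCtrl cells and all 80 in siFOXO1 cells were kept. For the siRNA this held for 3 of 21 in static cells and 14 of 27 under LSS. Of 226 results not called, 203 of 5565 alternative values gained the call. The cause of these changes was not tested. Depth of 11.91 to 16.87 M reads limits calls at low levels, and simulated 1.5-fold changes were recovered in at most 23.1% of genes in comparisons of 2 groups. The planned count tests were not run.

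Genes changed by FOXO1 siRNA in static cells numbered 47 and became 25 with the stricter filter, 14 and 73 with pseudocounts of 0.1 and 2 and 351 with only the libraries of the comparison. FOXO1 in static cells lost its call with the stricter filter (-1.187) and the pseudocount of 0.1 (-1.191). With only the libraries of the comparison the siRNA under LSS called 0 genes by limma, so both overlaps with it were 0 and 0, and FOXO1 (-2.226) lost its call. The overlap of siRNA calls was 29 with quantile normalization, which gave 1 gene for the interaction, and 10 with the pseudocount of 0.1.

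With the replicate block LSS changed 7512 genes in siCtrl and 7751 in siFOXO1 cells, 6407 shared, and the siRNA changed 110 genes in static cells, 314 under LSS and 609 averaged, with 65 shared and 123 opposite to LSS. With the replicate block within each shear condition the counts were 494, 1228 and 1755, with 287 shared, 40 for the interaction and 8 lists for the siRNA under LSS. Without both LSS replicate 3 libraries they were 170, 221 and 607, with 57 shared, 98 opposite, 1 for the interaction and 8 lists under LSS and 9 for the interaction. The interaction had 0 lists with no filter and 5 with the stricter filter. With an estimated correlation 0 lists were called in any comparison, and with fry 0 for the siRNA in static cells, under LSS and the interaction, 16 for LSS in siFOXO1 cells and 2 for the averaged siRNA effect.

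With 1 library left out, genes ranged from 5559 to 7128 for LSS in siCtrl cells, 5786 to 7393 in siFOXO1 cells, 3 to 89 for the siRNA in static cells (without siFOXO1 static replicate 2 and siCtrl LSS replicate 3), 33 to 181 under LSS (without siFOXO1 LSS replicate 2 and siCtrl LSS replicate 3), 0 to 2 for the interaction and 174 to 418 averaged (without siFOXO1 static replicate 2 and siCtrl LSS replicate 3). Overlaps ranged from 3 to 31 for the siRNA, 4938 to 5698 for LSS and 14 to 91 for opposite calls. FOXO1 ranged from -1.313 to -1.028 in static cells and -2.396 to -1.902 under LSS. Lists ranged from 10 to 11, 3 to 6, 2 to 8, 8 to 9, 0 to 5 and 3 to 7 for LSS in siCtrl cells, the siRNA in static cells and under LSS, LSS in siFOXO1 cells, the interaction and the averaged siRNA effect.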

Other observations

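The siRNA effect averaged over both conditions, a comparison and a test chosen after the data were seen, changed 332 genes, 164 up and 168 down, and 86 of them by at least 2-fold. The genes below were chosen after their values were seen. Besides ACSM3 (-2.39, SE 0.19), SEMA3G (-2.21, SE 0.18), FABP4 (-2.14, SE 0.18), A2M (-1.83, SE 0.18) and IFI44L (2.33, SE 0.21), it lowered the imprinted gene PEG10 (-0.85, SE 0.09, adjusted p = 0.000421), the amino acid transporter gene SLC7A7 (-1.03, SE 0.12) and CD55, an inhibitor of complement (-0.90, SE 0.11). PTGS1 (1.18, SE 0.16, adjusted p = 0.0025), EMCN (0.72, SE 0.09) and OAS2 (1.65, SE 0.21) rose. The count was 609 with the replicate block, 1755 with the block within each condition and 607 without both LSS replicate 3 libraries. It was 176, 176 and 200 without siCtrl static replicates 1, 2 and 3 and 201, 174 and 205 without siFOXO1 static replicates 1, 2 and 3.

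Of 19 flow-induced genes 3 rose and 0 fell (7 and 0 adjusted over the list alone; median 0.40, camera adjusted p = 9.06e-07, and adjusted p = 0.171 with an estimated correlation; fry 0.026). Only the real split, 1 of 100, gave a median as far from 0 (0.399, highest other 0.357). That is the smallest share these splits can give. It concerns 1 of 24 lists in a comparison added after seeing the data, so chance is not excluded. Of 29 interferon genes 9 rose and 0 fell (9 and 1 adjusted over the list alone; median 0.44, adjusted p = 8.73e-10, and adjusted p = 0.314 with an estimated correlation; fry 0.0396). Epithelial and mesothelial markers (median 0.73, adjusted p = 0.000768, and adjusted p = 0.314 with an estimated correlation) and mesenchymal genes (median 0.25, adjusted p = 0.0103, and adjusted p = 0.34 with an estimated correlation) were called up, with 1 of 5 and 2 of 25 members up and 0 down (4 and 0, and 4 and 1, adjusted over the list alone). The mesenchymal call was lost without siCtrl LSS replicate 2 (adjusted p = 0.0522) and siFOXO1 static replicate 1 (0.0528). ER stress was called down with 0 of 23 genes called by limma (median -0.18, adjusted p = 0.0475, and adjusted p = 0.781 with an estimated correlation) and was lost without siCtrl static replicate 1 (0.119), siCtrl LSS replicates 1 (0.107) and 2 (0.29), siFOXO1 static replicates 2 (0.0843) and 3 (0.136) and siFOXO1 LSS replicate 3 (0.61; median -0.01). Median-of-ratios scaling (0.0544), no scaling (0.0585), the stricter filter (0.0615) and a pseudocount of 0.1 (0.0563) ended it too. The number of lists was 3 without siCtrl LSS replicate 2.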
